A study of Homo sapiens with 9 samples.

How the data were processed

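Gene expression was measured in normal human bronchial epithelial cells grown in air-liquid interface (ALI) culture, a system in which airway cells are grown on a porous support until they touch and are then fed from below with their upper surface exposed to air. There were 9 arrays, 3 from subconfluent cultures, 3 from confluent cultures and 3 from cultures at day 28 of ALI. Per the labels' protocols, the apical medium was removed at confluence and the basal medium was replaced by a differentiation medium, so time, air exposure and medium changed together between the confluent and the day 28 cultures. Each stage is also a harvest of its own, so a batch tied to a harvest and the stage cannot be told apart.

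Per the labels' protocols, 100 ng of total RNA was labelled with a 3′ in vitro transcription kit and hybridised to an Affymetrix array. The authors deposited log2 values for 54675 probe sets, made with RMA in Affymetrix Expression Console per the submitters' processing notes; the versions are not given in the sources used here. RMA subtracts background, brings the arrays to a common distribution and summarises the probes of a set. It gives no detection calls, and values near background are compressed, so folds of genes that start near the floor are understated. Since all arrays were brought to the same distribution, a change in the total amount of messenger RNA cannot be seen in the deposited log2 values. For arrays the number of replicates, here 3 per group, limits the precision, and no read depth exists. All 3 deposited values of a stage are identical for 602 probe sets in subconfluent, 866 in confluent and 414 in day 28 cultures. The cause was not tested, and limma's moderated variance draws on all genes.

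Of the probe sets, 62 were array controls, 41091 had exactly 1 gene symbol in the probe annotation, 1801 had several and 11721 had none there. Gene IDs of 41037 probe sets matched a RefSeq gene table (assembly GRCh38.p14, used for names only), and 0 symbols differed. Probe sets with several symbols or none named no gene. Each gene was represented by the probe set with the highest mean over all 9 arrays, which left 19739 genes, 10510 of them with several probe sets. Genes linked to sex were left out. Among the genes with several probe sets, calls in both directions were found for 12 genes between confluent and subconfluent cultures, 519 genes between day 28 and confluent cultures and 657 genes between day 28 and subconfluent cultures.

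Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a model of 3 group means over all 9 arrays, with Benjamini-Hochberg adjustment within each of 3 comparisons. A gene was called at an adjusted p under 0.05, and a further count required a change of at least 2-fold, a log2 difference of 1. A contrast of the 2 steps (day 28 minus confluent, less confluent minus subconfluent) tested whether they differed. Values are given as log2 differences ± SE, or as means ± SD, always with n = 3 arrays per group. Nothing in the labels says whether the replicates came from separate donors or cultures, so the p-values measure only the spread between these arrays, which may be technical.

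Before the data were examined, 41 gene lists, the tests, the alternatives and the rule for named genes were fixed. Of 1123 list memberships, 1018 were measured. Lists were tested with camera at its preset correlation of 0.01, which asks whether a list moved relative to the other genes, with adjustment over the 41 lists. The same test with a correlation estimated from the data is given where it changes the call. In the text a list "rose" or "fell" only where camera at the preset called it, and members are counted by the limma calls. Named genes were, per comparison, the 10 largest increases and the 10 largest decreases among called genes whose groups did not overlap, 24 fixed genes, and from each list up to 4 members with the largest change together with members that went against the list. Of the fixed genes, TP63 was not among the genes tested, so no value is given for it.

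The calculation was tested on simulated data made from the real means and spreads of the 19739 genes, with noise independent between genes. In each comparison 67 genes were changed by 0.5 on the log2 scale, 67 by 1 and 66 by 2. Far more genes were called in the real data, so recovery there may differ. For confluent against subconfluent cultures it recovered 70.1% of genes changed by 0.5 on the log2 scale, 95.5% of those changed by 1 and 100% of those changed by 2, with 5.35% of calls false. For day 28 against confluent cultures the figures were 67.2%, 97.0% and 100%, with 4.35% false, and for day 28 against subconfluent cultures 62.7%, 97.0% and 100%, with 4.42% false.

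The alternatives were the mean of a gene's probe sets, leaving out probe sets marked for possible cross-hybridisation, a filter at the 40th percentile of all probe set means (3.79 on the log2 scale), scaling to a list of housekeeping genes, cyclic loess, a fit on only the 6 arrays compared, trended and robust moderation, array weights, the replicate number as a block, each array left out, limma's treat, a 1.5-fold rule, fry, and lists without shared members. Scaling to the Bacillus subtilis poly-A control probe sets, and the use of the alternatives on the difference between the steps, were added after seeing the data. The labels do not say whether these controls were added to the RNA.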

Results

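The 9 arrays followed human bronchial epithelial cells through 3 stages of culture: 3 arrays of subconfluent cells, 3 of confluent cells and 3 of cells at day 28 of air-liquid interface (ALI) culture. The series title states the purpose, to follow RNA changes as these cells differentiate. The comparisons covered the arrival at confluence, the change from confluence to day 28, and both together.

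The stages stood apart on the arrays. Correlations over all probe sets between arrays of the same stage ran from 0.995 to 0.998, against 0.994 to 0.995 between subconfluent and confluent arrays and 0.911 to 0.928 between day 28 and earlier arrays. The leading principal component held 94.2% of the variance and set day 28 apart, and the next, with 2.69%, parted subconfluent from confluent arrays. The median gene SD was 0.07 in subconfluent, 0.08 in confluent and 0.11 in day 28 cultures on the log2 scale. The ACTB control probe sets, which report how far the signal drops from the 3′ to the 5′ end of the beta-actin transcript, differed by 1.96 ± 0.07 (SD, n = 3) in subconfluent, 2.22 ± 0.19 in confluent and 3.02 ± 0.14 in day 28 cultures. For GAPDH the differences were 0.35 ± 0.02, 0.39 ± 0.13 and 0.58 ± 0.22, and for the poly-A controls 2.20 ± 0.14, 2.33 ± 0.14 and 2.39 ± 0.16.

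**Figure D1:**
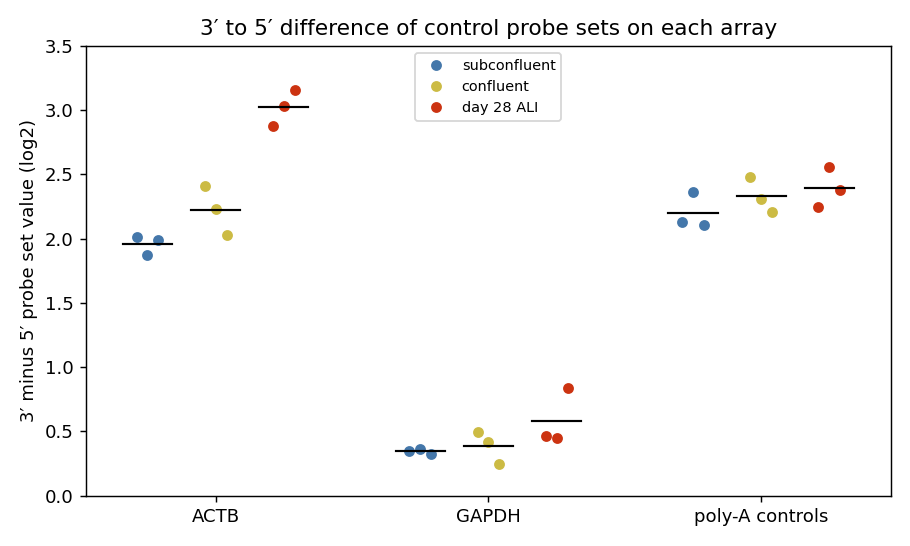
Difference between the 3′ and the 5′ control probe sets (log2) on each of the 9 arrays, for ACTB, GAPDH and the mean of the poly-A controls; points are arrays and lines are means of 3. The ACTB difference was 3.02 at day 28 against 2.22 at confluence, while the poly-A control means were 2.39 and 2.33.

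As cultures became confluent, genes of cholesterol synthesis and of xenobiotic and oxidant metabolism rose, and genes of mitosis, interferon response and inflammation fell. As lists, only the genes of mitosis kept their call with an estimated correlation (adjusted p = 0.0122, against 0.0607 for cholesterol synthesis and NRF2 targets, 0.0888 for xenobiotic metabolism, 0.149 for interferon and 0.0822 for inflammation), and with scaling to the poly-A controls the medians of the interferon and inflammation lists were above 0, at 0.10 and 0.11. That scaling moved the median of all genes to 0.39 in this step, so both lists still lay below the typical gene. CYP1B1, a cytochrome P450 that oxidises xenobiotics and oestrogens, rose by 4.09 ± 0.11 on the log2 scale (17.1-fold, adjusted p = 4.8e-08). AKR1B10, an aldo-keto reductase, rose by 3.03 ± 0.10 (adjusted p = 9.05e-08) and KRT15, a basal cell keratin, by 2.14 ± 0.07 (adjusted p = 9.39e-08). The decoy interleukin-1 receptor IL1R2 fell by 4.79 ± 0.17 (27.6-fold, adjusted p = 1.95e-07), from 10.18 ± 0.03 (SD, n = 3) to 5.39 ± 0.24, and IL13RA2, a decoy receptor for interleukin-13, fell by 2.67 ± 0.12 (adjusted p = 6.36e-07). Other large increases were those of GPNMB (2.44), MAF (2.44), SERPINB13 (2.38), NUPR1 (2.24), EGR1 (2.17) and TMT1A (2.09), and other large decreases those of ADAMTS6 (-1.92) and the matrix metalloproteinases MMP9 (-1.72) and MMP10 (-1.72).

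In the cholesterol synthesis list 17 of 19 measured genes rose and none fell (18 rose when adjusted over the list alone; camera adjusted p = 4.78e-20, adjusted p = 0.0607 with an estimated correlation). HMGCS1, which makes the HMG-CoA used by the rate-limiting step, rose by 2.12 ± 0.07, the sterol sensor INSIG1 by 1.80, DHCR7 by 1.29 and MSMO1 by 1.19. In xenobiotic and aldehyde metabolism 16 of 38 genes rose and 2 fell (17 and 2 adjusted over the list alone; camera adjusted p = 6.07e-08, adjusted p = 0.0888 with an estimated correlation). After CYP1B1 and AKR1B10 came the aldehyde dehydrogenase ALDH3A1, from 6.51 to 8.51 (adjusted p = 6.36e-07), and AKR1C3 (1.83), while SULT1E1 (-0.38) and CYP2J2 (-0.29) fell. Among NRF2 targets 11 of 22 rose (11 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.43e-06, adjusted p = 0.0607 with an estimated correlation). They included GCLC (0.87), which makes the precursor of glutathione, and PGD (0.70). In glycolysis and hypoxia 12 of 28 rose (12 adjusted over the list alone; camera adjusted p = 4.54e-08, adjusted p = 0.0822 with an estimated correlation). Risers were DDIT4 (1.24), NDRG1 (1.14), ENO2 (1.09) and the glucose transporter SLC2A1 (0.98).

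The list of G2 and M phase genes fell, with 26 of 35 members lower and none higher (31 lower adjusted over the list alone), at a median of -0.43 (camera adjusted p = 2.5e-19, adjusted p = 0.0122 with an estimated correlation), although none was called either way with scaling to the poly-A controls (median -0.037, against 0.39 over all genes). The mitotic kinases AURKB (-0.75), PLK1 (-0.66) and BUB1 (-0.65), the ubiquitin-conjugating enzyme UBE2C (-0.74) and CDC20 (-0.65) changed most. TOP2A fell by 0.46 ± 0.12 (adjusted p = 0.0317), and MKI67 differed by -0.11 ± 0.10 (adjusted p = 0.533). In DNA replication and S phase 11 of 39 genes fell and CCNE2 (0.32) rose (15 and 2 adjusted over the list alone; camera adjusted p = 8.32e-05, adjusted p = 0.144 with an estimated correlation), although 2 rose and 0 fell with scaling to the poly-A controls. RPA2 (-0.53), GINS3 (-0.50), POLA2 (-0.40) and CDC45 (-0.39) fell, and the replicative helicase subunit MCM2 differed by 0.02 ± 0.09 (adjusted p = 0.935).

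Interferon-induced genes fell as a list, with 12 of 34 lower and 3 higher (20 and 4 adjusted over the list alone; camera adjusted p = 1.33e-08, adjusted p = 0.149 with an estimated correlation), and 9 lower and 4 higher at a median of 0.10 with scaling to the poly-A controls. With that scaling the median of all genes was 0.39 in this step. The largest decreases were in the chemokine CXCL11 (-2.47 ± 0.35, with an SD of 0.89 over the confluent arrays), IFIT2 (-1.95 ± 0.09), IFIT1 (-1.64), IFIT3 (-1.63) and RSAD2 (-1.59). IFITM1 (0.62), GBP1 (0.36) and PSMB9 (0.30) rose. Of 27 inflammatory cytokines and chemokines 12 fell and 3 rose (14 and 4 adjusted over the list alone; camera adjusted p = 0.000169, adjusted p = 0.0822 with an estimated correlation), but 6 fell and 5 rose at a median of 0.11 with scaling to the poly-A controls. CCL5 (-1.95), CXCL5 (-1.47), CXCL3 (-1.34) and the prostaglandin synthase PTGS2 (-1.23) fell. IL33 (1.17), the interleukin-1 receptor antagonist IL1RN (0.86) and LIF (0.33) rose. IL1B differed by -0.30 ± 0.12 (adjusted p = 0.126). YAP targets fell in 8 of 20 genes, with MYOF (0.28) higher (9 and 1 adjusted over the list alone; camera adjusted p = 0.000403, adjusted p = 0.144 with an estimated correlation), but 1 fell and 1 rose at a median of 0.16 with scaling to the poly-A controls. The largest decreases were in CCN1 (-1.06), DLC1 (-0.79) and FJX1 (-0.67). Epithelial-mesenchymal transition and wound genes fell in 10 of 33, with TGFBI (0.39) higher (10 and 2 adjusted over the list alone; camera adjusted p = 0.00148, adjusted p = 0.178 with an estimated correlation), although 5 rose and 3 fell with scaling to the poly-A controls. VIM, the mesenchymal intermediate filament vimentin, fell by 0.62 ± 0.10.

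Several further lists rose at confluence, none of which kept its call with an estimated correlation. In the squamous and cornified envelope list 11 of 33 genes rose and 3 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.00107, adjusted p = 0.0607 with an estimated correlation). SERPINB3 rose by 2.08 ± 0.15, KRT13 by 1.62 ± 0.13, KRT4 by 1.30 and the cross-linking enzyme TGM1 by 1.13 ± 0.10. TMPRSS11D (-0.65), ECM1 (-0.42) and CRCT1 (-0.33) fell. Goblet cell and mucin genes rose in 8 of 26, none falling (8 adjusted over the list alone; camera adjusted p = 0.00123, adjusted p = 0.0607 with an estimated correlation). CLCA4 (1.14) and CLCA2 (1.07) led. Innate defence secretions rose in 7 of 26 (10 adjusted over the list alone; camera adjusted p = 0.00695, adjusted p = 0.144 with an estimated correlation). The calprotectin subunits S100A8 (1.51) and S100A9 (1.09) led. Ion and fluid transport genes rose in 8 of 31 with 2 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.00677, adjusted p = 0.0888 with an estimated correlation). The sodium channel subunit SCNN1A (1.49 ± 0.07) and the water and glycerol channel AQP3 (1.69) rose, and ANO1 (-0.60) and KCNMA1 (-0.44) fell. Oxidative phosphorylation genes rose in 4 of 30 (6 adjusted over the list alone; camera adjusted p = 0.00225, adjusted p = 0.414 with an estimated correlation), led by NDUFA2 (0.38). Markers of ciliated cells were not called as a list, with 3 of 22 higher and 1 lower (adjusted p = 0.575), nor were secretory (club) cell markers, with 5 of 21 higher and 3 lower (adjusted p = 0.392), or basal cell markers, with 4 of 21 higher and 2 lower (adjusted p = 0.504). FOXJ1, DNAI1, DNAH5, SCGB1A1, BPIFA1, MUC5AC, MUC5B, KRT5, KRT14, IVL, CDH1, CFTR, DICER1 and NOTCH3 did not pass, with differences between -0.29 (KRT14) and 0.23 (SCGB1A1).

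Over all 19739 genes, limma called 2977 between confluent and subconfluent cultures, 1745 higher and 1232 lower at confluence, and 152 of them by at least 2-fold, 112 higher and 40 lower. Groups of 3 did not overlap for 35.3% of genes, where chance gives 10%. Camera called 20 of 41 lists, 13 up and 7 down, of which only the G2 and M phase list was called with an estimated correlation. Without confluent replicate 2 the count of called genes was 1915. The count of at least 2-fold changes was 101 without probe sets marked for cross-hybridisation, and with scaling to the poly-A controls it was 407, of which 95.8% were higher against 73.7% as deposited, and of all called genes 98.2% against 58.6%. With that scaling 2117 genes were called.

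Between confluence and day 28 of ALI, genes of motile cilia, of airway secretions and of antigen presentation rose and genes of the cell cycle, basal cells and matrix attachment fell. The lists of basal cells (adjusted p = 0.254 with an estimated correlation) and of hemidesmosome and basement membrane (adjusted p = 0.0845 with an estimated correlation) did not keep their calls under that alternative. PIGR, the receptor that carries polymeric immunoglobulins across epithelia, rose by 10.63 ± 0.06 on the log2 scale (adjusted p = 4.45e-15), from 2.87 ± 0.06 (SD, n = 3) to 13.51 ± 0.03. The secreted proteins MSMB (10.34 ± 0.11), BPIFA1 (10.09 ± 0.12), STATH (9.66 ± 0.08), BPIFB1 (9.41 ± 0.11) and SCGB3A1 (9.12 ± 0.11) and the ciliated cell genes AGR3 (9.99 ± 0.11), SNTN (9.44 ± 0.09), CFAP95 (9.38 ± 0.12) and CDC20B (9.12 ± 0.09) made up the rest of the 10 largest increases, each with an adjusted p of 5.97e-13 or lower. The largest decreases were in AMIGO2 (-6.31 ± 0.10, adjusted p = 2.07e-12), the ecto-nucleotidase NT5E (-6.27 ± 0.13), the alarmin cytokine IL1A (-6.17 ± 0.11), the protease inhibitor SERPINE2 (-6.06 ± 0.09) and the matrix protein THBS1 (-6.02 ± 0.13), followed by FEZ1, LIPG, FST, ZBED2 and SRPX at -6.01 to -5.52.

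Ciliated cell markers rose in 21 of 22 measured genes (22 adjusted over the list alone), with a median of 4.99 (camera adjusted p = 6.04e-16, adjusted p = 0.0302 with an estimated correlation). Structural genes of the motile cilium rose in 42 of 46, none falling (42 adjusted over the list alone; camera adjusted p = 4.11e-20, adjusted p = 0.0302 with an estimated correlation). Among them were the radial spoke gene RSPH1 (8.20), CFAP43 (7.08) and the dynein intermediate chain DNAI1 (4.30 ± 0.08). The outer arm heavy chain DNAH5 rose from 4.92 to 7.92 (adjusted p = 1.73e-08). The ciliogenesis factor FOXJ1 rose by 1.95 ± 0.20 (adjusted p = 5.97e-06), from 4.45 to 6.39. Regulators of multiciliogenesis rose in 8 of 15, including DEUP1 (4.58), MYB (4.13) and CCNO (2.77). The centriole duplication genes STIL (-0.97), CEP152 (-0.48) and PLK4 (-0.40) fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.00465, adjusted p = 0.207 with an estimated correlation). Intraflagellar transport genes rose in 27 of 30 and BBS7 (-0.57) fell (27 and 1 adjusted over the list alone; camera adjusted p = 1.41e-10, adjusted p = 0.126 with an estimated correlation). IFT172 (3.32), IFT27 (2.69) and IFT22 (2.58) led.

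Secretory (club) cell markers rose in 20 of 21 genes, with a median of 5.40 (20 adjusted over the list alone; camera adjusted p = 2.27e-15, adjusted p = 0.0191 with an estimated correlation). SCGB1A1, the club cell secretoglobin, rose by 7.23 ± 0.18 and RARRES1 by 8.05. Of 26 goblet cell and mucin genes 17 rose and 4 fell (17 and 4 adjusted over the list alone; camera adjusted p = 3.66e-05, adjusted p = 0.0191 with an estimated correlation). The membrane mucins MUC4 (7.19), MUC15 (6.65), MUC1 (6.59) and MUC20 (6.37) rose, and the fallers were GALNT5 (-2.63), TMEM45A (-1.09), CLCA2 (-0.69) and SPDEF (-0.76), a transcription factor of goblet cells. The gel-forming mucin MUC5B rose by 1.03 ± 0.09 to 4.96 ± 0.11 (SD, n = 3), with its other probe set at -0.14, and MUC5AC differed by 0.21 ± 0.13 (adjusted p = 0.206), its 4 probe sets lying between -0.23 and 0.21. Innate defence secretions rose in 19 of 26 genes and fell in CCL20 (-0.85) and RNASE7 (-0.69) (21 and 2 adjusted over the list alone; camera adjusted p = 9.31e-09, adjusted p = 0.0191 with an estimated correlation), with complement factor CFB at 7.83. MHC class II presentation rose in all 11 genes (11 adjusted over the list alone), with a median of 4.68 (camera adjusted p = 1.2e-09, adjusted p = 0.0191 with an estimated correlation). The members included HLA-DRA (8.84 ± 0.15), HLA-DQA1 (6.33), HLA-DPA1 (5.88), the protease CTSS (5.19), the invariant chain CD74 (4.68 ± 0.10) and the transactivator CIITA (1.90). Probe sets of HLA paralogs can share signal, so single HLA values are uncertain.

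**Figure D2:**
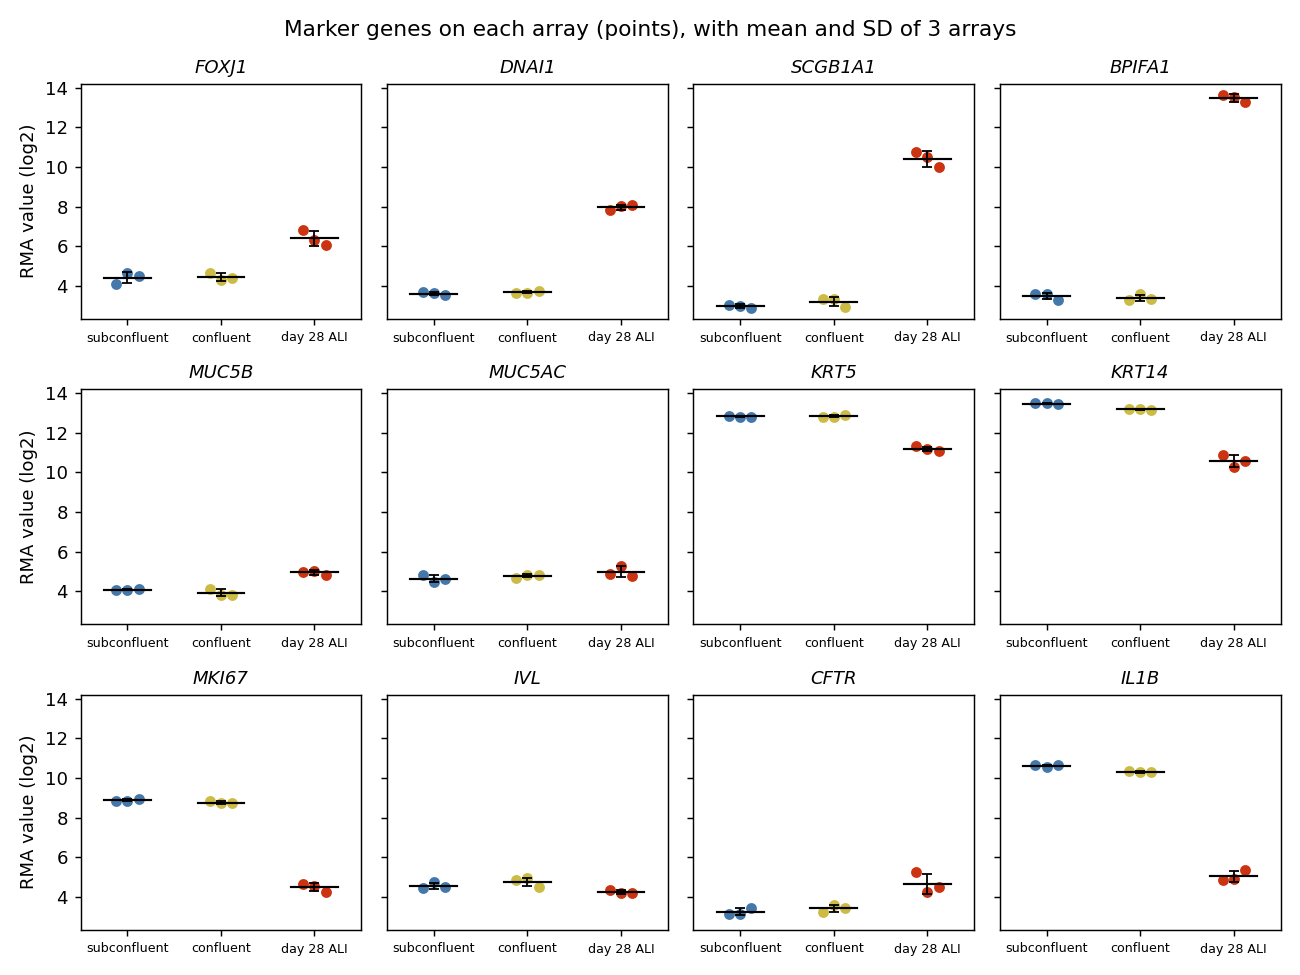
Log2 RMA values of 12 marker genes on each of the 9 arrays; points are arrays, horizontal lines are means and error bars are SD of 3 arrays per group. SCGB1A1 stood at 3.20 at confluence and 10.42 at day 28 and MKI67 at 8.76 and 4.48, while MUC5AC lay between 4.64 and 4.99 in the group means.

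Xenobiotic and aldehyde metabolism genes rose in 30 of 38, with CYP2S1 (-1.26) and CYP1A1 (-1.03) lower (30 and 3 adjusted over the list alone; camera adjusted p = 1.59e-10, adjusted p = 0.037 with an estimated correlation). GSTA1, a glutathione transferase, rose by 8.16, the alcohol dehydrogenase ADH1C by 7.64, the aldehyde dehydrogenase ALDH1A1 by 6.80, the cytochrome P450 CYP4B1 by 5.77 and ALDH3A1 by 1.95 ± 0.09. Of 31 ion and fluid transport genes 22 rose and 7 fell (22 and 7 adjusted over the list alone; camera adjusted p = 0.000344, adjusted p = 0.0302 with an estimated correlation). The phosphate transporter SLC34A2 and the proton pump ATP12A each rose by 7.05, KCNE1 by 5.77, SCNN1A by 1.24 ± 0.07 and the chloride channel CFTR by 1.23 ± 0.21 (adjusted p = 0.000423). The calcium-activated chloride channel ANO1 (-4.12), CA2 (-2.58), KCNN4 (-2.09), ADORA2B (-1.88), P2RY2 (-1.64), CA12 (-1.56) and SLC12A2 (-0.35) fell. Tight and adherens junction genes rose in 19 of 26 (19 adjusted over the list alone; camera adjusted p = 6.25e-05, adjusted p = 0.0191 with an estimated correlation), but 8 rose and 6 fell at a median of -0.03 with scaling to the poly-A controls. With that scaling the median of all genes was -0.62 in this step. CLDN8 (6.87), TJP3 (4.04) and CGN (2.98) rose most, while TJP1 (-0.78) and CTNNB1 (-0.49) fell and E-cadherin, CDH1, differed by -0.07 ± 0.09 (adjusted p = 0.539). Oxidative phosphorylation genes rose in 24 of 30 with 2 lower (24 and 2 adjusted over the list alone; camera adjusted p = 3.11e-05, adjusted p = 0.223 with an estimated correlation), although 2 rose and 6 fell with scaling to the poly-A controls. NDUFA2 (1.64) and COX5B (1.13) led, and ATP5MC1 (-0.53) and UQCRC1 (-0.20) fell.

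All 35 measured G2 and M phase genes fell (35 adjusted over the list alone), with a median of -3.10 (camera adjusted p = 6.4e-21, adjusted p = 0.00943 with an estimated correlation). Among them were the proliferation marker MKI67 (-4.28 ± 0.10), NCAPG (-4.18), AURKB (-4.07), BIRC5 (-3.88) and the topoisomerase TOP2A (-2.74 ± 0.12). In DNA replication and S phase 38 of 39 genes fell (38 adjusted over the list alone; camera adjusted p = 3.97e-20, adjusted p = 0.0191 with an estimated correlation). The list includes MCM10 (-5.23), CDC6 (-4.51), RRM2 (-4.30) and MCM2 (-3.07 ± 0.09).

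Basal cell markers fell in 16 of 21 genes (16 lower and 4 higher adjusted over the list alone; camera adjusted p = 3.11e-05, adjusted p = 0.254 with an estimated correlation). Only 21 of the 28 genes in the list were measured, and TP63 was not among them. The fallers included SNAI2 (-3.49), the integrin ITGA3 (-3.02), CAV1 (-2.65), KRT14 (-2.60 ± 0.12) and KRT5 (-1.64 ± 0.07), the last from 12.83 to 11.20. MMP10 (1.93), AQP3 (0.88) and KRT15 (0.81) rose. Hemidesmosome and basement membrane genes fell in 18 of 20 (18 adjusted over the list alone; camera adjusted p = 2.4e-08, adjusted p = 0.0845 with an estimated correlation). After THBS1 came the collagens COL4A2 (-4.21) and COL4A1 (-3.82) and the laminin LAMB1 (-4.03). Epithelial-mesenchymal transition and wound genes fell in 24 of 33 (25 lower and 4 higher adjusted over the list alone; camera adjusted p = 8.77e-07, adjusted p = 0.0781 with an estimated correlation). Fallers included MMP1 (-5.35), EREG (-4.73), VCAN (-4.50) and VIM (-4.45 ± 0.10), whose other probe set gave -0.03. The collagen cross-linker LOX (2.78), CCN2 (2.32), MMP10 and MMP13 (1.10) rose. YAP targets fell in 12 of 20, with NT5E, AXL (-4.55) and FJX1 (-3.76) first, and CCN2, GADD45B (1.02) and RBMS3 (0.31, its probe sets between -0.29 and 0.62) higher (12 and 3 adjusted over the list alone; camera adjusted p = 0.00324, adjusted p = 0.2 with an estimated correlation).

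Inflammatory cytokines and chemokines fell in 17 of 27 genes and rose in 4 (17 and 4 adjusted over the list alone; camera adjusted p = 0.00651, adjusted p = 0.137 with an estimated correlation). After IL1A came IL1B (-5.29 ± 0.12), IL33 (-3.35) and PTGS2 (-3.17), and the risers were CXCL6 (3.20), CCL28 (2.13), TSLP (1.21) and NFKBIA (1.02). The interferon list went the other way, with 22 of 34 genes higher and 7 lower (22 and 7 adjusted over the list alone; camera adjusted p = 0.000755, adjusted p = 0.328 with an estimated correlation), but 13 higher and 11 lower at a median of -0.02 with scaling to the poly-A controls. With that scaling the median of all genes was -0.62 in this step. GBP2 (4.25), MX1 (2.90), XAF1 (2.64) and IFI44L (2.58) rose and CXCL11 (-2.55), OAS3 (-1.48), ISG15 (-0.61), OASL (-0.55), CXCL10 (-0.52), TAP1 (-0.51) and IFITM3 (-0.28) fell. Cholesterol synthesis fell in 15 of 19 genes, with HMGCS1 (-2.01 ± 0.07), LSS (-1.85) and DHCR7 (-1.66), and TM7SF2 (2.01) higher (16 and 1 adjusted over the list alone; camera adjusted p = 2.34e-05, adjusted p = 0.2 with an estimated correlation). Glycolysis and hypoxia genes fell in 21 of 28 and rose in 5 (21 and 5 adjusted over the list alone; camera adjusted p = 0.000199, adjusted p = 0.147 with an estimated correlation). VEGFA (-1.70), NDRG1 (-1.51) and PFKFB4 (-1.49) fell, and LOX, ANKRD37 (2.25), MXI1 (1.31), EGLN3 (0.57) and BNIP3L (0.32) rose.

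The squamous and cornified envelope list was not called at day 28 against confluence (adjusted p = 0.453). In it 13 of 33 genes rose and 9 fell (13 and 9 adjusted over the list alone), and with scaling to the poly-A controls 7 rose and 19 fell. SERPINB3 (6.47), SERPINB4 (5.42), KRT4 (4.49) and KRT13 (3.17 ± 0.13) rose and DSC2 (-2.52), KRT16 (-1.97), TGM1 (-0.96 ± 0.10) and involucrin, IVL (-0.53 ± 0.11), fell. The microRNA processing list was not called either (adjusted p = 0.0864), with 10 of 21 genes lower and 5 higher (10 and 5 adjusted over the list alone), and 8 lower and 10 higher with housekeeping scaling. GEMIN4 (-1.68), the GTPase RAN (-1.45) and the small RNA effector AGO2 (-1.37) fell, DDX17 (0.62) and DDX5 (0.60) rose. DICER1 differed by -0.02 ± 0.09 (adjusted p = 0.86). Its 6 probe sets lay between -0.43 and 0.06. NRF2 targets were higher in 8 of 22 and lower in 8 (adjusted p = 0.686), 13 higher and 6 lower with housekeeping scaling and 2 higher and 14 lower with scaling to the poly-A controls, with the cystine transporter SLC7A11 at -3.43 and GPX2 at 1.12. Notch pathway genes were higher in 8 of 25 and lower in 5 (adjusted p = 0.551), and 4 higher and 16 lower with scaling to the poly-A controls. HES6 (2.78) rose, HES2 (-2.49), JAG1 (-1.68) and NOTCH1 (-1.65) fell. NOTCH3 differed by -0.16 ± 0.07 (adjusted p = 0.0673), its 2 probe sets at -0.16 and 1.22. Cytosolic ribosomal protein genes were lower in 11 of 30 and higher in none (6 lower adjusted over the list alone; adjusted p = 0.0749), but higher in 17 and lower in none with housekeeping scaling. Housekeeping genes were lower in 13 of 23 and higher in 6, with a median of -0.42 (adjusted p = 0.0864). They were lower in 12 and higher in 10 with housekeeping scaling, which sets only the mean of the list, and lower in 16 and higher in 0 with scaling to the poly-A controls.

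Markers of other cell types were not called as lists between day 28 and confluence. Fibroblast and mesenchymal markers were lower in 8 of 23 and higher in 1 (adjusted p = 0.0708), and 7 higher and 6 lower with housekeeping scaling. SPARC (-3.81) fell with VIM, and S100A4 (3.71) rose. Endothelial markers changed in 4 of 15, with 2 each way (adjusted p = 0.991), 8 higher and 1 lower with housekeeping scaling and 0 higher and 13 lower with scaling to the poly-A controls. Leukocyte markers were higher in 5 of 23 and lower in 1 (adjusted p = 0.453), with KIT (4.08), CD14 (2.04) and LYN (1.41) among the risers and the pan-leukocyte PTPRC at 0.06. Alveolar epithelial markers were higher in 5 of 15 and lower in 1 (adjusted p = 0.271), with SLC34A2 and AQP5 (4.61), which also sit in the transport list, ahead. Ionocyte markers were higher in 6 of 13 and lower in 2 (adjusted p = 0.0749), including ATP6V1C2 (4.12) and HEPACAM2 (1.89). Neuroendocrine markers were higher in 1 of 12 and lower in 2 (adjusted p = 0.453), with UCHL1 at -2.92. Tuft cell markers were higher in 3 of 11 and lower in 1 (adjusted p = 0.518), with POU2F3 at 1.19. With scaling to the poly-A controls, lower calls outnumbered higher ones in the leukocyte, alveolar, ionocyte and tuft lists, and with housekeeping scaling higher calls outnumbered lower ones in the neuroendocrine list.

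**Figure D3:**
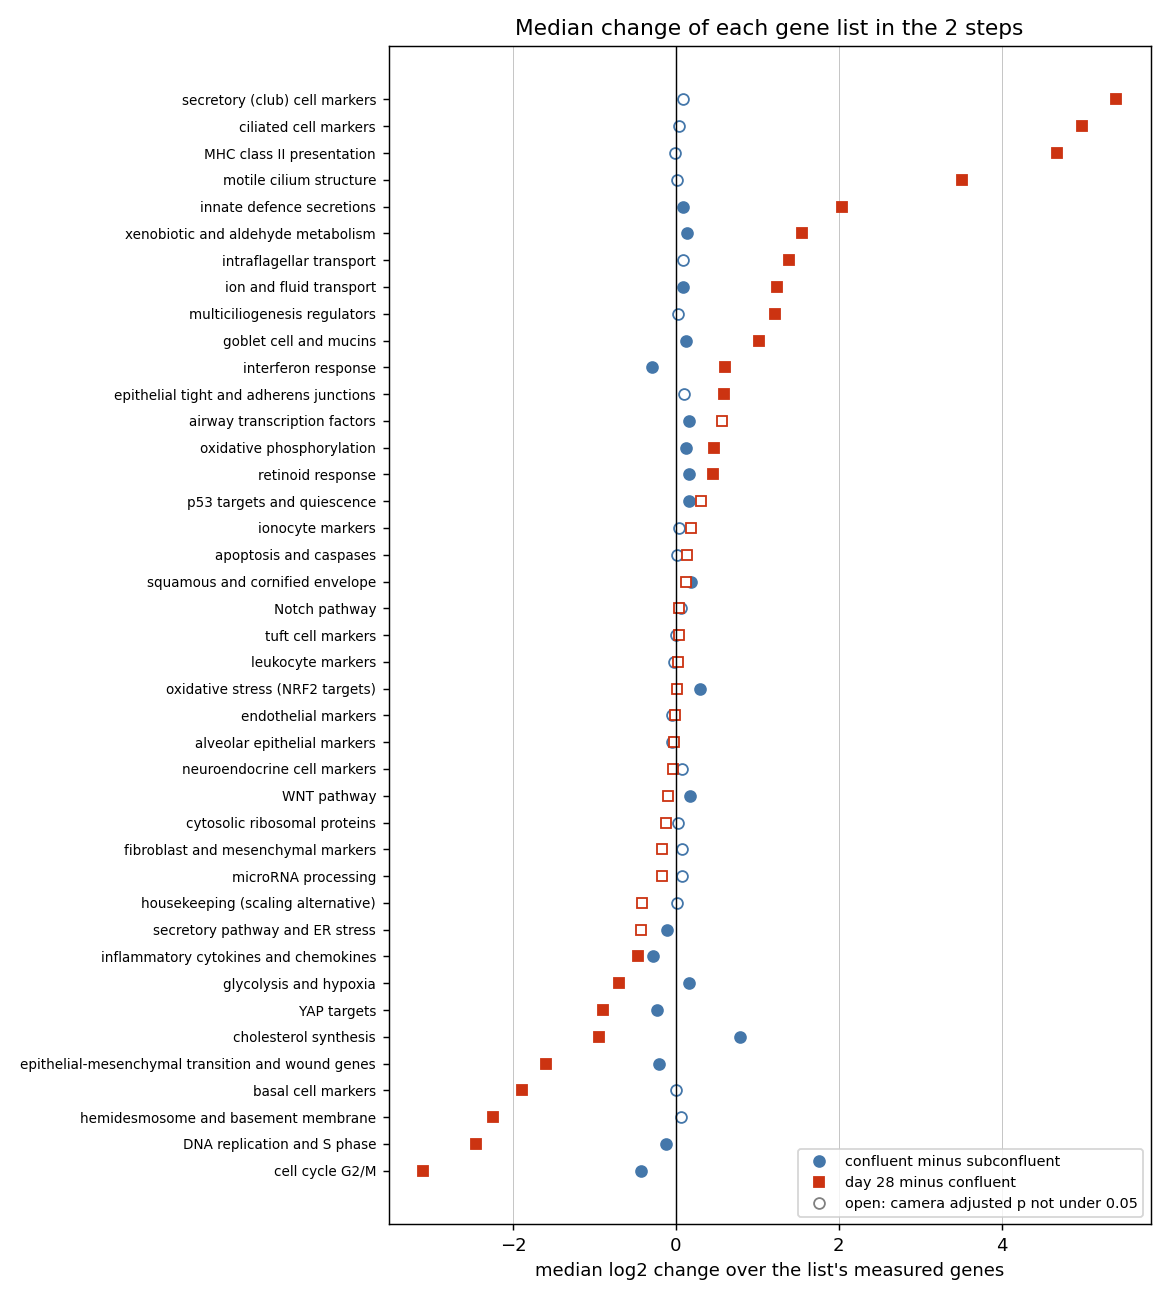
Median log2 change over the measured genes of each of the 41 lists, from subconfluent to confluent (circles) and from confluent to day 28 (squares); filled symbols have a camera adjusted p under 0.05. The medians from confluence to day 28 run from -3.10 for G2 and M phase to 5.40 for club cell markers, and those from subconfluence to confluence from -0.43 to 0.79.

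In total limma called 10474 genes between day 28 and confluence, 5113 higher and 5361 lower, and 3658 by at least 2-fold, 1948 higher and 1710 lower. Groups of 3 did not overlap for 56.7% of genes, where chance gives 10%. Camera called 23 lists, 14 up and 9 down, 11 of them also with an estimated correlation. The balance of directions rests on the scaling between arrays: 48.8% of called genes were higher as deposited, 76.3% with housekeeping scaling and 11.7% with scaling to the poly-A controls, which moved the median of all genes by 0.28 and -0.62, so the changes given here are relative to the typical gene. Of those of at least 2-fold the shares were 53.3%, 68.3% and 21.7%. The number of called genes moved as well, from 10474 as deposited to 15129 with housekeeping scaling and 15163 with scaling to the poly-A controls.

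Over the whole course, from subconfluent cultures to day 28, the same 10 genes led the increases as from confluence, with MSMB (10.56 ± 0.11) and PIGR (10.51 ± 0.06) ahead. The largest decreases were in IL1A (-7.03 ± 0.11), IL1R2 (-6.81 ± 0.17), AMIGO2 (-6.76 ± 0.10), NT5E (-6.62) and THBS1 (-6.61), followed by SERPINE2, FEZ1, FST, the growth factor NRG1 (-6.04) and the cadherin CDH11 (-5.98). KRT15, unlike KRT5 (-1.63 ± 0.07) and KRT14 (-2.89 ± 0.12), ended higher than it began, by 2.95 ± 0.07 (adjusted p = 3.5e-11). HMGCS1 lay 0.11 ± 0.07 above its start (adjusted p = 0.222; its other probe set -0.94) and TGM1 0.16 ± 0.10 above (adjusted p = 0.18). The fixed markers FOXJ1 (1.98), DNAI1 (4.36), DNAH5 (3.07), SCGB1A1 (7.46), BPIFA1 (9.99), MUC5B (0.88), KRT13 (4.78), ALDH3A1 (3.95), SCNN1A (2.74) and CFTR (1.42, its probe sets between -0.24 and 1.42) were higher, and MKI67 (-4.39), TOP2A (-3.20), MCM2 (-3.05), VIM (-5.08), IL1B (-5.59), IVL (-0.33) and NOTCH3 (-0.22, its other probe set 1.62) lower. MUC5AC passed at 0.35 ± 0.13 (adjusted p = 0.0382) in 1 of its 4 probe sets, while CDH1 (0.07 ± 0.09) and DICER1 (0.15 ± 0.09, its 6 probe sets between -0.31 and 0.25 with 1 called each way) did not pass.

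Limma called 10901 genes over this course, 5454 higher and 5447 lower, and 4085 by at least 2-fold, 2218 higher and 1867 lower. Camera called 24 lists, 15 up and 9 down, 11 also with an estimated correlation. The cholesterol list was not called over the course, with 5 of 19 genes higher and 8 lower (adjusted p = 0.86), and 10 higher and 3 lower with housekeeping scaling. The interferon list was not called either, with 17 of 34 higher and 12 lower (adjusted p = 0.33). GBP2 (4.63) ended above its start and CXCL11 (-5.01), ISG15 (-1.64) and IFIT2 (-1.40) below it. Among inflammatory genes 21 of 27 fell and 5 rose (camera adjusted p = 0.000184, adjusted p = 0.0533 with an estimated correlation). Of the called genes 50.0% were higher as deposited, 74.9% with housekeeping scaling and 37.4% with scaling to the poly-A controls, and of those of at least 2-fold 54.3%, 68.1% and 41.9%. The called genes numbered 10901, 14808 and 7473 in the same order.

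Many genes were called in both steps. Of these, 947 rose in both, 892 fell in both, 537 rose and then fell and 193 fell and then rose, where independent lists of the same lengths would share 452, 335, 474 and 319. Simulated unchanged groups that shared the confluent arrays gave 0 genes in each class. That simulation held no changed genes, so few calls were bound to follow, and it is no yardstick for these counts. Over all genes the changes of the 2 steps had a correlation of 0.21 and a covariance of 0.06, and 52.0% of genes had the same sign. The simulation gave -0.50, -0.0055 and 33.2%, which is what a shared group gives where no gene changed. These values therefore do not test the observed ones, and genes are not independent replicates. The confluent arrays are too few to be split, and sharing them pushes the steps in opposite directions, which would add to both opposite classes. Genes that rose and then fell exceeded their share, 537 against 474, but those that fell and then rose did not, 193 against 319. These shares treat all 19739 genes, dim genes included, as equally open to a call. An excess over such a share is therefore no sign by itself that the steps are linked. How much of either count comes from the sharing cannot be told here. GPNMB (2.44 and 2.14) and SERPINB3 (2.08 and 6.47) rose in both steps, IL13RA2 (-2.67 and -2.79), CXCL11 (-2.47 and -2.55) and ADAMTS6 (-1.92 and -2.13) fell in both. HMGCS1 (2.12 and -2.01) rose and then fell, and MMP10 (-1.72 and 1.93) fell and then rose. The contrast between the steps was called for 7773 genes. It was 10.76 for PIGR (adjusted p = 1.1e-12), -4.12 for HMGCS1 (adjusted p = 1.76e-09) and -0.05 for ALDH3A1 (adjusted p = 0.824). With scaling to the poly-A controls the balance turned, with 610 genes moving the same way in both steps and 899 in opposite ways, against 1839 and 730 as deposited. That scaling set the median change of all genes at 0.39 in the first step and -0.62 in the second. By construction it pushes every gene to rise and then fall, so the turn says nothing about single genes. At a minimum of 2-fold in each step, 60 genes moved the same way and 34 in opposite ways. Without confluent replicate 2, 1186 genes moved the same way in both steps, and the count that moved in opposite ways was 468, against 459 to 473 without each of the subconfluent replicates.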

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

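Both results in this part come from probe sets outside the gene comparisons, and all tests of explanations here were chosen after the results were seen. Among the 11721 probe sets with no gene symbol in the annotation, limma called 321 at least 2-fold higher at day 28 than in subconfluent cultures and 391 at least 2-fold lower. Between confluence and day 28 the largest increases among them were 7.53, in a probe set whose 3 confluent values are identical, and 6.03 (adjusted p = 1.33e-13), and the largest decreases -5.33 and -5.20. These probe sets were not assigned to genes here. The ACTB control probe sets, whose 3′ value exceeded the 5′ value by 3.02 at day 28, are the other signal outside the comparisons.

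The ACTB 3′ to 5′ difference grew by 0.80 ± 0.14 (SE, n = 3 arrays per group) from confluence to day 28. Shorter labelled product on all transcripts would enlarge the difference of the poly-A controls as well, but that grew by 0.060 ± 0.12, less than the growth of ACTB by more than its spread. This holds only if those controls were added to the RNA before labelling, which the labels do not state. More degraded RNA at day 28 is left open: the GAPDH difference grew by 0.20 ± 0.15, and the groups overlap. Compression of the bright 3′ probe set is left open too: the 5′ probe set fell by 1.93 ± 0.16 for each unit of fall of the 3′ one at day 28, which by itself restates the growth, and by 1.99 ± 0.42 at confluence, too wide a spread to test whether the steps match. A biological change of transcript form was not tested.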

How the results depend on the processing

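Scaling to the poly-A controls, and all alternatives for the difference between the steps, were chosen after seeing the data. Over all alternatives, 9005 comparisons of named genes kept their call or lack of it, 260 were no longer called and 59 became called. A further 30 changed direction with a call before or after the change. Changes of sign between 2 values that were not called were counted as kept. For the lists, which were not retested with poly-A control scaling, cyclic loess, probe set means or array weights, among others, the numbers are 1736, 64, 45 and 0. A change of direction was counted only for lists called in the main fit. Where values changed, the cause was not tested, apart from what an alternative does by construction. The confluent against subconfluent count of at least 2-fold changes (152) was 101 without probe sets marked for cross-hybridisation, 407 with poly-A control scaling, 41 with treat and 571 at 1.5-fold, where day 28 gave 6107 against confluent and 6611 against subconfluent cultures in place of 3658 and 4085. Genes called in both steps in the same direction (1839) numbered 610 with poly-A control scaling and 60 at 2-fold in each step, those in opposite directions (730) 899 with poly-A control scaling and 34 at 2-fold, and genes differing between the steps (7773) 14240 with poly-A control scaling. By construction that scaling pushes all genes up in the first step and down in the second. With an estimated correlation 1, 11 and 11 lists were called, in place of 20, 23 and 24, and fry, which tests each list by itself, called 40 for day 28 against confluent and 39 against subconfluent cultures.

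With each array left out, called genes ranged from 1915 to 3478 for confluent against subconfluent, 9788 to 10325 for day 28 against confluent and 10256 to 10731 for day 28 against subconfluent cultures. Changes of at least 2-fold ranged from 144 to 165, 3605 to 3726 and 4073 to 4127, and lists called from 19 to 20, 23 to 24 and 23 to 24. Genes moving the same way in both steps ranged from 1186 to 2137, opposite ways from 459 to 836, and those differing between the steps from 6702 to 7966. With the replicate number as a block, the called genes were 2638, 10374 and 10803 in the same order, 1631 and 638 in both steps, and 7594 differing between the steps. Deviations of arrays with the same number correlated at -0.0574 to 0.0509, with 0 pairs over 0.1, so the numbers gave no sign of pairing.

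With the mean of all probe sets, the day 28 minus confluent change was -0.23 for ELOVL5 and 0.53 for NOTCH3, and the day 28 minus subconfluent change -0.42 for HMGCS1, -0.068 for MUC5AC and 0.70 for NOTCH3. With housekeeping scaling, day 28 minus confluent was 0.26 for DICER1, 0.052 for SREBF1 and 0.075 for UQCRC1, and day 28 minus subconfluent 0.062 for ATP5MC1, 0.19 for MYOF and 0.048 for NOTCH3. With poly-A control scaling, confluent minus subconfluent was 0.057 for CRCT1, 0.10 for CYP2J2, 0.17 for FEZ1, 0.013 for SULT1E1, 0.13 for FAS, 0.067 for GADD45B and 0.045 for WNT5B. Day 28 minus confluent was then -0.32 for ACSS2, -0.30 for BNIP3L, -0.0011 for DDX17, -0.016 for DDX5, -0.045 for EGLN3, -0.44 for ELOVL5, -0.068 for IFIT2, -0.48 for IFIT3, -0.53 for PGD, -0.56 for PTPRC, -0.31 for RBMS3 and -0.31 for PLK2. Values near background are compressed, so changes of dim genes can be understated. MUC5AC, at group means of 4.64 to 4.99, lay above the cutoff of the dim filter (3.79), and whether compression limited its change was not tested.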

Other observations

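The tests on housekeeping and MHC class II genes were chosen after those results were seen, and the tests on fatty acid genes, aryl hydrocarbon receptor targets and other splits before. Transcription factors of the airway epithelium rose as a list by confluence, with 8 of 27 genes higher and none lower (9 adjusted over the list alone; limma calls, camera adjusted p = 0.000242, adjusted p = 0.117 with an estimated correlation). ELF3 (1.07), GRHL1 (0.87), GRHL3 (0.79) and SOX2 (0.75) led. From confluence to day 28 the list was not called (adjusted p = 0.0708), with 14 higher and 9 lower, and 11 higher and 13 lower with scaling to the poly-A controls. ELF3 (4.67), TFCP2L1 (3.26), SOX2 (3.03) and ELF5 (2.85) rose while SOX9 (-3.63), SOX7 (-2.83), SOX15 (-2.66) and FOXA2 (-2.34) fell. Retinoid response genes rose in both steps, with 7 of 19 higher at confluence, CRABP2 (1.19) ahead (8 adjusted over the list alone; camera adjusted p = 0.000526, adjusted p = 0.0953 with an estimated correlation). At day 28 12 were higher than at confluence, with RARRES1 (8.05), DHRS9 (5.42) and PLAAT4 (4.92) ahead and the retinoic acid hydroxylase CYP26B1 (-2.77) lower (13 and 2 adjusted over the list alone, camera adjusted p = 0.000822, adjusted p = 0.0982 with an estimated correlation), although 7 were higher and 5 lower at a median of -0.16 with scaling to the poly-A controls. The median of all genes was then -0.62.

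WNT pathway genes rose at confluence in 10 of 32 with 3 lower (12 and 3 adjusted over the list alone; camera adjusted p = 0.00787, adjusted p = 0.149 with an estimated correlation), WNT10A (0.91) and VANGL2 (0.80) ahead and DKK1 (-0.51), WNT7A (-0.40) and WNT5B (-0.35) lower. They were not called at day 28 against confluence (adjusted p = 0.189), with 7 higher and 13 lower, and 14 higher and 11 lower with housekeeping scaling. WNT4 (3.52) and WNT5A (2.27) rose and the secreted antagonists SFRP1 (-4.52), DKK1 (-4.20) and DKK3 (-3.86) fell. Genes of p53 response and quiescence rose at confluence in 11 of 23 with 4 lower (11 and 4 adjusted over the list alone; camera adjusted p = 0.00677, adjusted p = 0.0944 with an estimated correlation), TP53INP1 (1.30) and the cyclin-dependent kinase inhibitor CDKN2B (1.19) ahead and PLK2 (-0.61), GADD45A (-0.41), GADD45B (-0.32) and FAS (-0.26) lower. At day 28 against confluence CDKN2B (3.04), TXNIP (2.70), TP53INP1 (2.14) and CDKN2A (1.82) rose and CDKN1A (-0.69) fell, in a list that was not called (adjusted p = 0.0622), with 13 higher and 6 lower, and 6 higher and 10 lower with scaling to the poly-A controls. Secretory pathway and ER stress genes were called lower at confluence (camera adjusted p = 0.0471, adjusted p = 0.286 with an estimated correlation) with SDF2L1 (-0.52) lower and EDEM1 (0.31) higher among 29 genes (1 each adjusted over the list alone). The median of the list was positive in that step with scaling to the poly-A controls, as was that of all genes (0.39). At day 28 against confluence the list was not called (adjusted p = 0.0579), with 7 higher and 15 lower. TRIB3 (-3.66) and HSP90B1 (-1.97) fell and XBP1 (2.44) and CREB3L1 (1.46) rose. Apoptosis and caspase genes were called in neither step (adjusted p = 0.392 and 0.465). In the later step 10 of 24 were higher and 6 lower, and 3 higher and 13 lower with scaling to the poly-A controls, with PMAIP1 (-1.30) lower at confluence and BCL2L11 (2.22) higher and BAX (-1.39) lower at day 28.

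The housekeeping list had a median change of -0.42 from confluence to day 28, with TFRC (-1.74), GAPDH (-1.16), HPRT1 (-0.97) and ACTB (-0.80) lower by limma. A shift of the whole array, or less messenger RNA per amount of total RNA at day 28, would each move all members alike. Since all arrays were brought to the same distribution, the deposited values cannot test whether either took place. The members did not move alike: 6 were called higher, among them CHMP2A (1.06) and B2M (0.82). None was called higher with scaling to the poly-A controls, but the distance between CHMP2A and TFRC stays the same under any such shift. A common shift by itself therefore does not give the differences among the members. Whether the total amount of messenger RNA changed is not settled: the poly-A control mean was 0.62 ± 0.23 (SE) higher at day 28 than at confluence but 0.23 ± 0.21 higher than in subconfluent cultures. The stage itself, with its changed metabolic genes and lower cell cycle genes, is a candidate explanation that was not tested apart from these.

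MHC class II genes rose by a median of 4.68 at day 28. Leukocytes in the cultures are argued against by PTPRC, which differed by 0.057 at a level of 2.49, and by TYROBP (-0.10) and FCER1G (-0.10), although KIT, CD14 and LYN rose. The leukocyte list had a median change of 0.03. Signal shared between HLA paralogs is argued against as the whole cause by CD74, which lies outside that family and rose by 4.68 ± 0.10. A rise within the epithelial cells is a hypothesis that is consistent with these values.

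The course of the cholesterol genes, higher at confluence and lower at day 28, led to the hypothesis that fatty acid synthesis genes share it. Of 8 further fatty acid genes measured, 5 were called higher at confluence and then lower at day 28, where 2.72% of all genes were: ACLY (0.91 and -1.81), ELOVL6 (0.72 and -2.96), FADS2 (1.11 and -1.80), ACACA (0.68 and -0.70) and the regulator SREBF1 (0.96 and -0.22). ACSS2 (1.31 and 0.30) and ELOVL5 (0.34 and 0.17) rose in both steps and MID1IP1 (0.14 and -0.18) passed in neither. The 4 probe sets of ELOVL5 lay between -0.96 and 0.26 in the later step, and SREBF1 was 0.052 in that step with housekeeping scaling. FASN (1.76 and -1.57), SCD (1.45 and -1.88) and PNPLA3 (1.87 and -1.52), which had been seen before, followed the same course. A shared lipid synthesis programme may therefore extend beyond the cholesterol genes, as a hypothesis on these arrays.

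The rise of CYP1B1 (4.09) and CYP1A1 (1.26) at confluence led to the hypothesis that targets of the aryl hydrocarbon receptor moved together. Of TIPARP and AHRR, named in advance, 0 were called higher: TIPARP differed by 0.08 ± 0.06 (adjusted p = 0.394) and AHRR by 0.09 ± 0.07 (adjusted p = 0.466). TIPARP was bright, at 10.74 and 10.83, and AHRR dim, at 2.81 and 2.90. TIPARP did not share the rise of CYP1B1, which went from 3.68 to 7.78. AHRR lay under the cutoff of the dim filter (3.79), so its lack of change says little. No other target was named in advance, so whether targets of the receptor moved together is left open.

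Other splits of the arrays were counted for each result. For each pair of stages the 6 arrays give 10 splits, so no share under 0.1 can be reached, and in each case 1 split, the real one, gave as many calls. The other splits called at most 0 genes by limma in each comparison, against 2977, 10474 and 10901, and at most 0 by at least 2-fold, against 152, 3658 and 4085. Each of these splits mixes the stages, which puts the difference between stages into the spread. Few gene calls were therefore bound to follow, and these counts test little. For the lists the highest other splits called 8 against 20 at confluence, 21 against 23 for day 28 against confluence and 18 against 24 over the whole course, so the number of lists called by camera at its preset correlation is also large in splits that mix the stages. Of 100 splits of all 9 arrays into 3 groups, 3 gave as many genes called in both steps as the real one, itself included, with a highest other of 9113 against 2569, and 3 as many genes with a difference between the steps, with a highest other of 10458 against 7773. In both counts all 3 lie among the 7 splits that kept the day 28 arrays together, so these counts do not exclude chance. The 2 splits that called more, 9107 and 9113 genes in both steps, made the day 28 arrays the group shared by the steps, which points to the distance of day 28 from the earlier stages as a structure of the arrays. The 4 other splits that kept the day 28 arrays together placed them at an end and called 0 genes in both steps, and the 93 that parted them at most 52.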
